A study of Mus musculus with 30 samples.

How the data were processed

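The data are RNA sequencing libraries of sorted mouse bone marrow cells, 30 in 7 groups of 4 or 6, each made from total RNA of 100 cells with the Nextera XT kit and read on a NextSeq instrument, per the sample labels. Per the file headers, each deposited file holds counts per gene, as total exon reads, unique exon reads and total intron reads. The reads were mapped to mm10 by the authors, per the submitters' processing notes, while the aligner and the counting program are not given in the sources used here. Each file holds 48737 entries for 46113 NCBI genes. Of these entries, 25149 are annotated with no exon and hold no exon reads, among them all 37 mitochondrial ones, whose reads are counted as intron reads. Reads on entries with no exon were 9.70% of all reads on average in untreated HSCs. The files also hold an expression value, equal to total exon reads in 22 libraries and to unique exon reads in the 8 libraries of the CD48 experiment, which was not used.

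Total exon reads were summed over entries of 1 gene identifier, which applied to 1931 genes with more than 1 entry, mostly copies on alternate loci (1.34 to 1.69% of exon reads). Unique reads were 80.7 to 83.1% of exon reads and introns took 56.2 to 67.6% of reads on genes. Of the identifiers, 97.1% were found in the NCBI gene table. Reads shared between near-identical genes, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, or genes with more than 1 entry, make the values of single members uncertain. Replicates were checked for duplicates: in every pair, counts of at least 20 differed by more than counting error (chi-square per degree of freedom 2.44 to 43.3).

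Groups, comparisons, tests, gene lists, the rule for named genes and a first set of other settings were fixed before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalisation, quasi-likelihood F tests, group means only), in 1 fit per experiment, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM are per library with TMM-scaled sizes, and errors are SD over libraries. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes whose groups did not overlap were counted in CPM. Where 1 group was at 0 in all libraries, the fold is a bound against 3 counts per library. Intervals and floors of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

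The 33 gene lists held 1065 genes, 50 of them in more than 1 list. They covered HSC identity, quiescence, cell division, metabolism, ribosomes, stress and immune responses, and markers of myeloid, megakaryocyte, erythroid, lymphoid, mast, endothelial, macrophage and stromal cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and the 148 p-values of 30 lists in 5 comparisons were adjusted together. Camera with an estimated correlation and fry were run beside it. The mitochondrially encoded list (13 genes, all with no exon), the sex-linked list and the sort gate list were not tested as lists. Single values per library, such as intron and mitochondrial shares, were compared by two-sided exact permutation tests, 25 in all.

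Named genes were chosen by rule. For each comparison they are the 6 largest rises and 6 largest falls among genes that passed, did not overlap between groups and had a mean log2 CPM of at least 5 in the higher group, without predicted genes and pseudogenes by name. To these come the 3 members with the smallest p in the direction of each called list, up to 2 members of lists not called, and Cd48, Slamf1, Procr, Tyms, Cdkn1a, Mki67 and Acly in every comparison. A part of these genes is printed, a few withheld for evaluation are not reported here or in the other settings, and any other gene is marked as chosen after its values were seen.

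The fits were tested on simulated data for the 2 groups of a comparison alone, with 66 or 67 genes changed at each fold. At folds of 1.5, 2 and 4 the share of changed genes recovered was 59.7, 87.9 and 98.5% for day 6, 37.3, 80.6 and 95.5% for day 10, 53.7, 95.5 and 100% for culture and 35.8, 85.1 and 97% for the CD48 comparison. Of the calls, 6.9, 4.1, 4.6 and 2% were false. For day 6, 5 of 5 raised lists of 30 genes and 0 of 100 unchanged lists were called by camera with either correlation. Simulated list members were independent, unlike the genes of real lists.

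The settings of that first set were RLE size factors, no filter on low counts, DESeq2 1.42.0, each library left out in turn, the replicate number as a block, all 30 libraries in 1 fit, the 2 groups alone, controls of the other experiment and the estimated correlation. After the data were seen, unique exon reads, intron reads, entries as deposited, fry, and a set of 8 libraries left out together were added. Those were libraries with transcripts of other cells or a strong stress or interferon signal, namely untreated replicate 3, day-6 replicate 1, day-10 replicates 3 and 6, uncultured replicates 1 and 4, CD48− replicate 3 and CD48+ replicate 3. The set left in other libraries with such signals. Among them were uncultured replicate 2 (megakaryocyte list mean 6.326 and immediate early 7.185 log2 CPM), uncultured replicate 3 (erythroid 5.942) and day-10 replicate 4 (erythroid 3.9). Calls kept without the set are therefore not shown to be free of such libraries. Settings meant for normalised values and for single transcripts did not apply to counts per gene.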

Results

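RNA was sequenced from 30 libraries, each of 100 cells sorted from bone marrow of C57BL/6 mice aged 8 to 10 weeks. Haematopoietic stem cells (HSCs) were sorted as CD150+CD48−EPCR+Lineage− cells and haematopoietic progenitor cells (HPCs) as CD150+CD48+EPCR+Lineage− cells. The 5-FU experiment held HSCs of untreated mice (n = 4) and HSCs taken 6 days (n = 4) and 10 days (n = 6) after 5-fluorouracil (5-FU), a pyrimidine analogue that kills dividing cells. The culture experiment held HSCs of untreated mice, either uncultured (n = 4) or cultured for 1 day (n = 4). The CD48 experiment held CD48− HSCs (n = 4) and CD48+ HPCs (n = 4), both taken 10 days after 5-FU. Expression is given below as CPM, read counts scaled to library size, and changes as log2 fold changes from edgeR with p-values adjusted by the Benjamini-Hochberg method. More or less mRNA below means a higher or lower share of a library's reads, not an amount per cell.

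The libraries held 5.21 to 12.2 M exon reads. The group means were 6.09 ± 0.705 M (SD) in untreated, 7.15 ± 0.804 in day-6, 7.55 ± 0.813 in day-10, 6.13 ± 0.558 in uncultured and 7.58 ± 1.08 in cultured HSCs. They were 8.54 ± 1.28 M in CD48− HSCs and 10.7 ± 1.38 in CD48+ HPCs. Between 14158 and 15406 genes were detected per library. Across genes, the Pearson correlation of log2 CPM between replicates was 0.939 to 0.986, where genes are not independent replicates. Reads counted for Lars2, a mitochondrial leucyl-tRNA synthetase gene, were 1.70 ± 0.346% of exon reads in untreated HSCs and 2.13 ± 0.0998% in cultured HSCs. Whether all of them come from Lars2 mRNA was not tested, so the shares are not read as its expression. Among sex-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty were detected in all 30 libraries. The first principal component held 27.4% of the variance of the 2000 most variable genes and the second 20.5%.

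**Figure D1:**
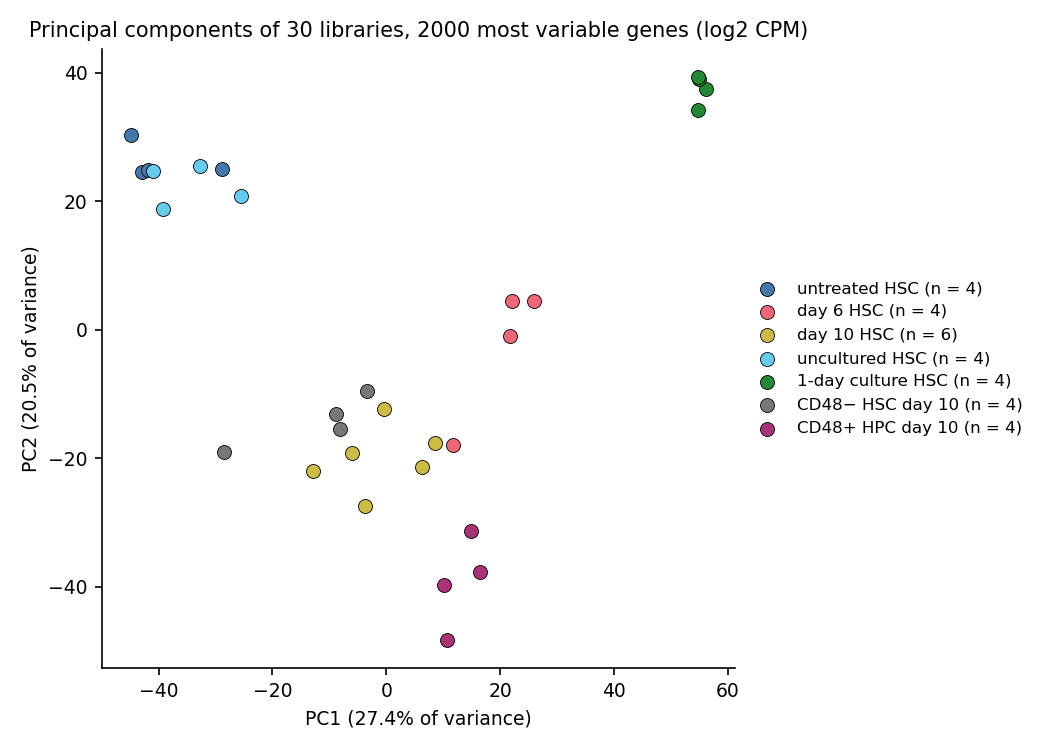
Principal components of the 30 libraries from log2 CPM of the 2000 most variable genes, PC1 on the x axis and PC2 on the y axis, one point per library and one colour per group. The 4 cultured libraries sit at PC1 54.7 to 56.2, and the 8 libraries of uncultured HSCs of untreated mice sit at PC1 -44.8 to -25.5.

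The first comparison asked how HSCs differed from untreated HSCs 6 days after 5-FU. Day-6 HSCs had more mRNA of DNA replication, mitosis, mitochondrial respiration and ribosome production genes, and less of HSC identity, quiescence and immediate early genes. These are calls of gene lists at a preset correlation between genes, and 0 of them held with an estimated correlation (adjusted p = 0.188 to 0.307). Mki67, a marker of cycling cells (gene 17345, mm10 chromosome 7, 135689788 to 135716409), was at 612 ± 27.3 CPM (SD, n = 4) against 168 ± 75.8 (n = 4) in untreated HSCs, a log2 change of 1.87 (adjusted p = 6.91e-06). The largest rise under the rule for named genes was that of Gem, a small GTP-binding protein (gene 14579, chromosome 4, 11704447 to 11714993), at 713 ± 62.9 against 21.7 ± 6.92 CPM. The adult beta-globin gene Hbb-bs (gene 100503605, chromosome 7, 103826523 to 103827928) fell from 1668 ± 745 to 9.42 ± 6.48 CPM, a log2 change of -7.47 that was -8.08 without day-6 replicate 2.

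All 56 measured DNA replication genes rose at day 6, and of 65 measured mitosis genes 64 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 7.67e-22 and 9.03e-23). They had adjusted p = 0.255 and 0.28 with an estimated correlation. Pole, the catalytic subunit of DNA polymerase epsilon (gene 18973, chromosome 5, 110286319 to 110337468), rose from 109 ± 11.7 to 317 ± 30.8 CPM, and Rrm1, a ribonucleotide reductase subunit, from 90.9 ± 17.9 to 343 ± 27.6. The mitotic genes Cdk1, Aurka, Cenpe and Pbk rose by 2.39, 2.30, 2.87 and 3.21 on the log2 scale. Of 34 measured genes of pyrimidine metabolism and 5-FU targets, 24 rose and 3 fell, or 25 and 5 adjusted over the list alone (adjusted p = 3.5e-06; adjusted p = 0.255 with an estimated correlation). Tyms, thymidylate synthase and the target of 5-FU, rose from 42.2 ± 13.5 to 118 ± 21.6 CPM. Cad, which starts pyrimidine synthesis, rose from 253 ± 20.8 to 704 ± 55.2 CPM.

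Of 77 nuclear oxidative phosphorylation genes 72 rose and 1 fell, and of 28 TCA cycle genes 26 rose (adjusted p = 1.31e-24 and 3.91e-11). Of 57 ribosome biogenesis and Myc target genes 50 rose and 1 fell, and of 23 glycolysis genes 13 rose and 3 fell (adjusted p = 2.12e-13 and 0.000932). With an estimated correlation these 4 lists had adjusted p = 0.188 to 0.307. Adjusted over the list alone, 72, 26, 53 and 13 genes of these lists rose and 1, 1, 1 and 3 fell. Ndufa4, a respiratory chain subunit, rose from 84.3 ± 3.64 to 232 ± 9.93 CPM, Mdh2, malate dehydrogenase, from 171 ± 16.2 to 395 ± 3.35, and Ldha, lactate dehydrogenase A, from 462 ± 55.6 to 1159 ± 44.2. Of 39 genes of the ATF4 and unfolded protein response 22 rose and 9 fell, and of 31 NRF2 target genes 12 rose and 2 fell, the same numbers as adjusted over the list alone (adjusted p = 0.00853 and 0.0252; adjusted p = 0.53 and 0.256 with an estimated correlation). The serine synthesis gene Psat1 rose by 1.49 on the log2 scale, and the peroxiredoxin gene Prdx1 by 1.38. In the same libraries the intron share of reads was 57.5 ± 0.864% against 65.1 ± 1.28%, and the mitochondrial mRNA share 0.329 ± 0.022% against 0.250 ± 0.0237%. Both had p = 0.0286 in a two-sided exact permutation test, the smallest p possible, and adjusted p = 0.0794 over 25 such tests. They are shares of the same reads, so a lower intron share can by itself raise the mitochondrial share.

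Of 50 HSC identity genes 33 fell and 1 rose, and of 30 quiescence genes 18 fell and 2 rose (adjusted p = 6.01e-07 and 0.000313; adjusted p = 0.255 and 0.307 with an estimated correlation). Adjusted over the list alone the numbers were 33 and 2, and 18 and 2. Adgrg1, an adhesion receptor (gene 14766, chromosome 8, 94974756 to 95014208), fell from 4531 ± 154 to 2094 ± 123 CPM. Pdzk1ip1 fell from 151 ± 3.56 to 34.8 ± 4.10 CPM, and Btg1, an antiproliferative gene, from 203 ± 27.8 to 64.0 ± 13.3. Of 30 immediate early genes, which respond within minutes to stimuli that include tissue handling, 25 fell and 1 rose, and of 31 inflammatory and NF-kB genes 15 fell and 2 rose, the same numbers as adjusted over the list alone. Their adjusted p-values were 9.8e-09 and 0.00938, and adjusted p = 0.262 and 0.528 with an estimated correlation. Ier2 fell from 271 ± 63.0 to 50.7 ± 9.66 CPM and Nfkbiz from 137 ± 28.2 to 51.9 ± 9.00. Of 25 megakaryocyte and platelet genes 13 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.0333; adjusted p = 0.496 with an estimated correlation).

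Markers of other cells moved too. Of 24 erythroid genes 19 fell and 1 rose, also adjusted over the list alone, with a median log2 change of -2.24 that was the same with genes at 0 set to their bound (adjusted p = 2.87e-05; adjusted p = 0.327 with an estimated correlation). Hba-a2 was at 0 in all 4 day-6 libraries and at 452 ± 204 CPM in untreated HSCs, at least 1070-fold lower against a floor of 3 counts per library, and Slc4a1 was at least 314-fold lower. Hba-a2 shares nearly its whole sequence with Hba-a1, so the division of reads between them is uncertain. Of 18 macrophage and monocyte genes 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (adjusted p = 0.0374; adjusted p = 0.679 with an estimated correlation). The macrophage receptor gene Csf1r, chosen after its values were seen, was at 95.9 CPM in day-6 replicate 1 and at 1.45, 6.07 and 10.5 in the other day-6 libraries. Mrc1 rose by 3.36 on the log2 scale and Lgmn by 2.84, and by 1.98 and 1.48 without day-6 replicate 1.

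No call was made for the remaining 14 lists at day 6 (camera adjusted p = 0.0817 to 0.98). Of 40 p53 target genes 15 rose and 11 fell, or 16 and 12 adjusted over the list alone (adjusted p = 0.694). Zmat3 rose from 16.6 ± 2.47 to 49.97 ± 5.12 CPM while Btg2 fell from 164 ± 67.6 to 9.84 ± 5.15. Cdkn1a, a cell cycle inhibitor with more than 1 entry in the files, was at 16.7 ± 7.09 against 6.82 ± 3.57 CPM (adjusted p = 0.0246). That call was lost without untreated replicate 2 or 4 or day-6 replicate 1 (adjusted p = 0.0711, 0.0721 and 0.0877), and with intron reads its log2 change was -0.18. The numbers that rose and fell were 9 and 7 of 26 fatty acid synthesis genes, 2 and 4 of 25 cholesterol synthesis genes, 14 and 3 of 29 fatty acid oxidation genes, and 24 and 9 of 79 cytosolic ribosomal protein genes. They were 0 and 3 of 50 interferon response genes, 5 and 8 of 27 hypoxia genes, 5 and 9 of 36 autophagy genes and 1 and 3 of 11 MHC class II genes. Among cell type lists they were 2 and 4 of 16 myeloid, 2 and 4 of 11 lymphoid, 0 and 2 of 6 mast cell, 4 and 7 of 17 endothelial and 1 and 1 of 9 stromal genes. Adjusted over the list alone, the numbers differed for cholesterol synthesis (1 and 3), ribosomal protein (22 and 9) and myeloid (1 and 4) genes and were the same for the other lists of these sentences. Median, mean and test differed in sign for the fatty acid synthesis, myeloid and endothelial lists. Of the sort gate genes, Cd48 was at 3.50 ± 1.85 against 0.431 ± 0.427 CPM (adjusted p = 0.00142), a log2 change of 3.02 that was 3.66 without untreated replicate 3. Slamf1, which encodes CD150, was at 35.6 ± 5.58 against 31.7 ± 4.62 CPM (adjusted p = 0.289), and Procr, which encodes EPCR, at 67.7 ± 3.75 against 74.5 ± 6.59 (adjusted p = 0.519).

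In all, 6622 of 12886 tested genes (51.4%) passed at day 6, 3308 higher and 3314 lower, of which 877 and 1106 changed at least 2-fold. The 4 day-6 and 4 untreated libraries did not overlap for 6250 genes (48.5%, against 2.86% by chance). With intron reads, counted as an alternative after the data were seen, calls were lost for oxidative phosphorylation, the TCA cycle, glycolysis, the ATF4, NRF2 and megakaryocyte lists (adjusted p = 0.0516 to 0.556). Leaving out 1 library ended the macrophage call (adjusted p = 0.0598, 0.146 and 0.0561 without untreated replicate 1 and day-6 replicates 1 and 4), the megakaryocyte call (0.0513 without untreated replicate 3) and the NRF2 call (0.0577 without day-6 replicate 1). Unique exon reads ended the megakaryocyte and macrophage calls (0.0502 and 0.0537), and fry the macrophage call (0.0907). Over all their alternatives the adjusted p of these 3 lists ran from 0.00195 to 0.679, 0.00355 to 0.496 and 2.2e-05 to 0.556.

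**Figure D2:**
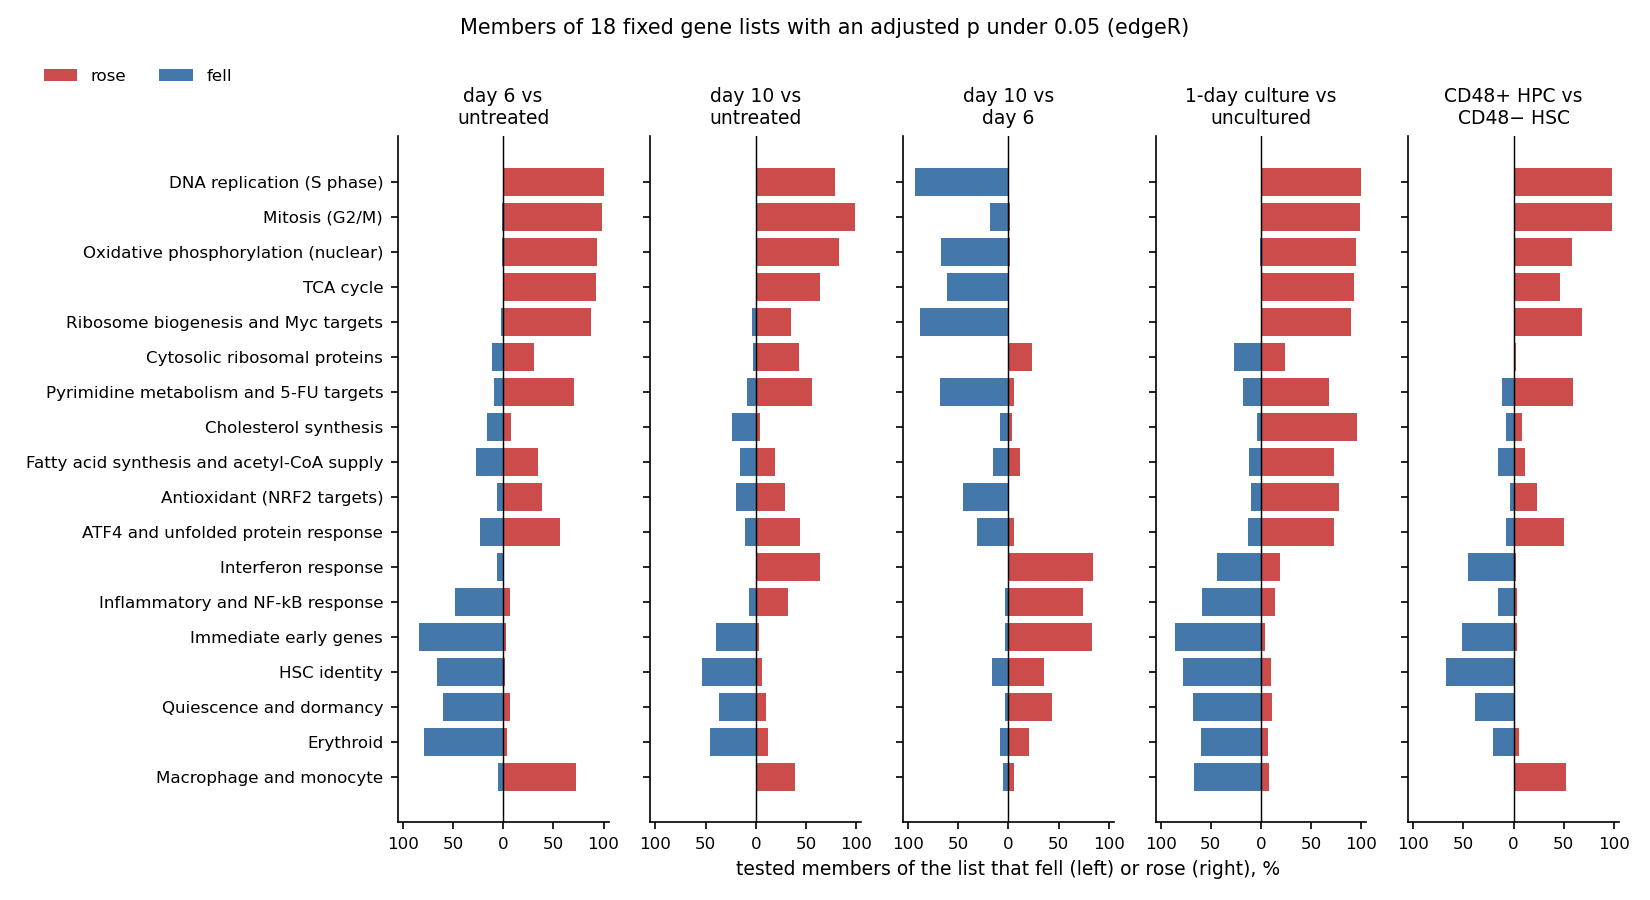
Members of 18 gene lists fixed before the data were examined that rose (red, right) or fell (blue, left) at an edgeR adjusted p under 0.05, as a percentage of the measured members on the x axis, for 5 comparisons. All 56 DNA replication genes rose at day 6, 44 at day 10, 56 in culture and 55 in CD48+ HPCs.

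The next comparison asked how HSCs differed from untreated HSCs 10 days after 5-FU. Mitosis genes were still raised at day 10, DNA replication and oxidative phosphorylation genes also rose, and interferon response genes rose as well. Of these 4 list calls 0 held with an estimated correlation (adjusted p = 0.255, 0.325, 0.255 and 0.571), and the median log2 change of the interferon list went from 1.354 to 0.667 without day-10 replicate 6. Mki67 was at 442 ± 47.6 CPM (SD, n = 6) against 168 ± 75.8 (n = 4), and Gem at 240 ± 131 against 21.7 ± 6.92. Selp, the adhesion molecule P-selectin (gene 20344, chromosome 1, 164115264 to 164150026), rose from 20.4 ± 8.34 to 371 ± 90.3 CPM, and Cd53, a leukocyte tetraspanin, from 18.2 ± 5.30 to 232 ± 50.4. Cyp26b1, a retinoic acid degrading enzyme, fell from 70.1 ± 28.6 to 1.34 ± 0.465 CPM.

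Of 65 mitosis genes 64 rose at day 10, and of 56 DNA replication genes 44 rose, or 64 and 48 adjusted over the list alone (adjusted p = 3.24e-27 and 9.44e-13; adjusted p = 0.255 and 0.325 with an estimated correlation). Cenpe rose from 7.86 ± 3.42 to 53.3 ± 11.5 CPM, Aurka from 9.70 ± 3.12 to 36.2 ± 5.64 and Mcm5, a replication helicase subunit, from 171 ± 13.9 to 343 ± 68.2. Tyms was at 66.9 ± 10.7 CPM (adjusted p = 0.0122), and 19 of 34 pyrimidine metabolism genes rose and 3 fell, or 21 and 3 adjusted over the list alone (adjusted p = 0.00216; adjusted p = 0.307 with an estimated correlation). Oxidative phosphorylation genes rose in 64 of 77 cases, TCA cycle genes in 18 of 28 and glycolysis genes in 11 of 23, with 0, 0 and 2 that fell (adjusted p = 8.57e-22, 4.84e-08 and 0.0104). The lists had adjusted p = 0.255, 0.255 and 0.274 with an estimated correlation, and adjusted over the list alone 68, 22 and 11 rose. Ndufa4 (gene 17992, chromosome 6, 11900373 to 11907446) was at 146 ± 13.3 CPM, Mdh2 at 288 ± 25.7 and Ldha at 901 ± 64.2. The intron share of reads was 60.1 ± 1.785%, below all 4 untreated libraries in all 6 (two-sided exact permutation p = 0.00476, the smallest possible, adjusted p = 0.0595).

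Of 79 cytosolic ribosomal protein genes 34 rose and 2 fell, and of 57 ribosome biogenesis genes 20 rose and 2 fell (adjusted p = 1.3e-05 and 0.00269; adjusted p = 0.552 and 0.679 with an estimated correlation). Adjusted over the list alone, 35 and 22 rose and 2 and 3 fell. Rpl27 rose by 0.55 on the log2 scale and Cad by 0.60. Of 39 ATF4 and unfolded protein response genes 17 rose and 4 fell, or 18 and 7 adjusted over the list alone (adjusted p = 0.0242; adjusted p = 0.552 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose from 4.87 ± 1.62 to 21.6 ± 9.73 CPM, and Vldlr from 15.0 ± 9.22 to 62.6 ± 23.6.

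Of 50 interferon response genes 32 rose and 0 fell, or 38 and 0 adjusted over the list alone, with a median log2 change of 1.35 (adjusted p = 2.9e-06; adjusted p = 0.571 with an estimated correlation). Oas2, an antiviral enzyme gene (gene 246728, chromosome 5, 120730333 to 120749874), rose from 54.5 ± 23.0 to 389 ± 273 CPM, and Lgals3bp from 266 ± 20.4 to 519 ± 177. The chemokine gene Cxcl10 rose from 0.351 ± 0.407 to 121 ± 191 CPM and was at 501 CPM in day-10 replicate 6, and its log2 change of 8.47 was 7.025 without that replicate and 9.08 without untreated replicate 3. The list's call was lost with fry, a test described below (adjusted p = 0.0657, range 2.11e-08 to 0.571 over its alternatives).

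HSC identity genes fell in 27 of 50 cases and rose in 3, quiescence genes fell in 11 of 30 and rose in 3, and immediate early genes fell in 12 of 30 and rose in 1 (adjusted p = 4.39e-07, 0.029 and 0.00561). With an estimated correlation they had adjusted p = 0.255, 0.539 and 0.557. Adjusted over the list alone 27, 11 and 12 fell and 3, 4 and 1 rose. Mmrn1 fell from 336 ± 27.5 to 85.6 ± 20.8 CPM and Egr1 from 1173 ± 436.5 to 280 ± 109. Of 24 erythroid genes 11 fell and 3 rose, or 12 and 3 adjusted over the list alone (adjusted p = 7.09e-05; adjusted p = 0.351 with an estimated correlation), and Hbb-bs fell to 5.32 ± 3.49 CPM. The erythroid list averaged 3.9 log2 CPM in day-10 replicate 4 against 1.694 to 1.93 in the other day-10 libraries, and without it the log2 changes of Hba-a1 and Slc4a1 went from -7.905 to -11.343 and from -8.969 to -10.884. Of 18 macrophage genes 7 rose and 0 fell, or 9 and 0 adjusted over the list alone (adjusted p = 0.0061; adjusted p = 0.57 with an estimated correlation), and Cd5l rose from 2.52 ± 1.02 to 13.9 ± 7.85 CPM.

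At day 10, 4893 of 12886 genes (38%) passed, 2560 higher and 2333 lower, of which 505 and 668 changed at least 2-fold. Libraries of the groups did not overlap for 3039 genes (23.6%, against 0.95% by chance). Median, mean and test differed in sign for the fatty acid synthesis, NRF2, MHC class II, myeloid, lymphoid and endothelial lists, none of them called. Cdkn1a was at 14.3 ± 7.68 CPM (adjusted p = 0.0548), and Slamf1 rose to 50.1 ± 4.05 CPM. With intron reads the calls for quiescence, pyrimidine metabolism, oxidative phosphorylation, the TCA cycle, glycolysis, both ribosome lists, ATF4 and macrophage genes were lost (adjusted p = 0.0633 to 0.967), and the log2 changes of Ndufa4 and Mdh2 were -0.042 and -0.045. The quiescence call was lost without untreated replicate 1 (adjusted p = 0.0771) and with the replicate block (0.0615, range 0.00978 to 0.539 over its alternatives).

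**Figure D3:**
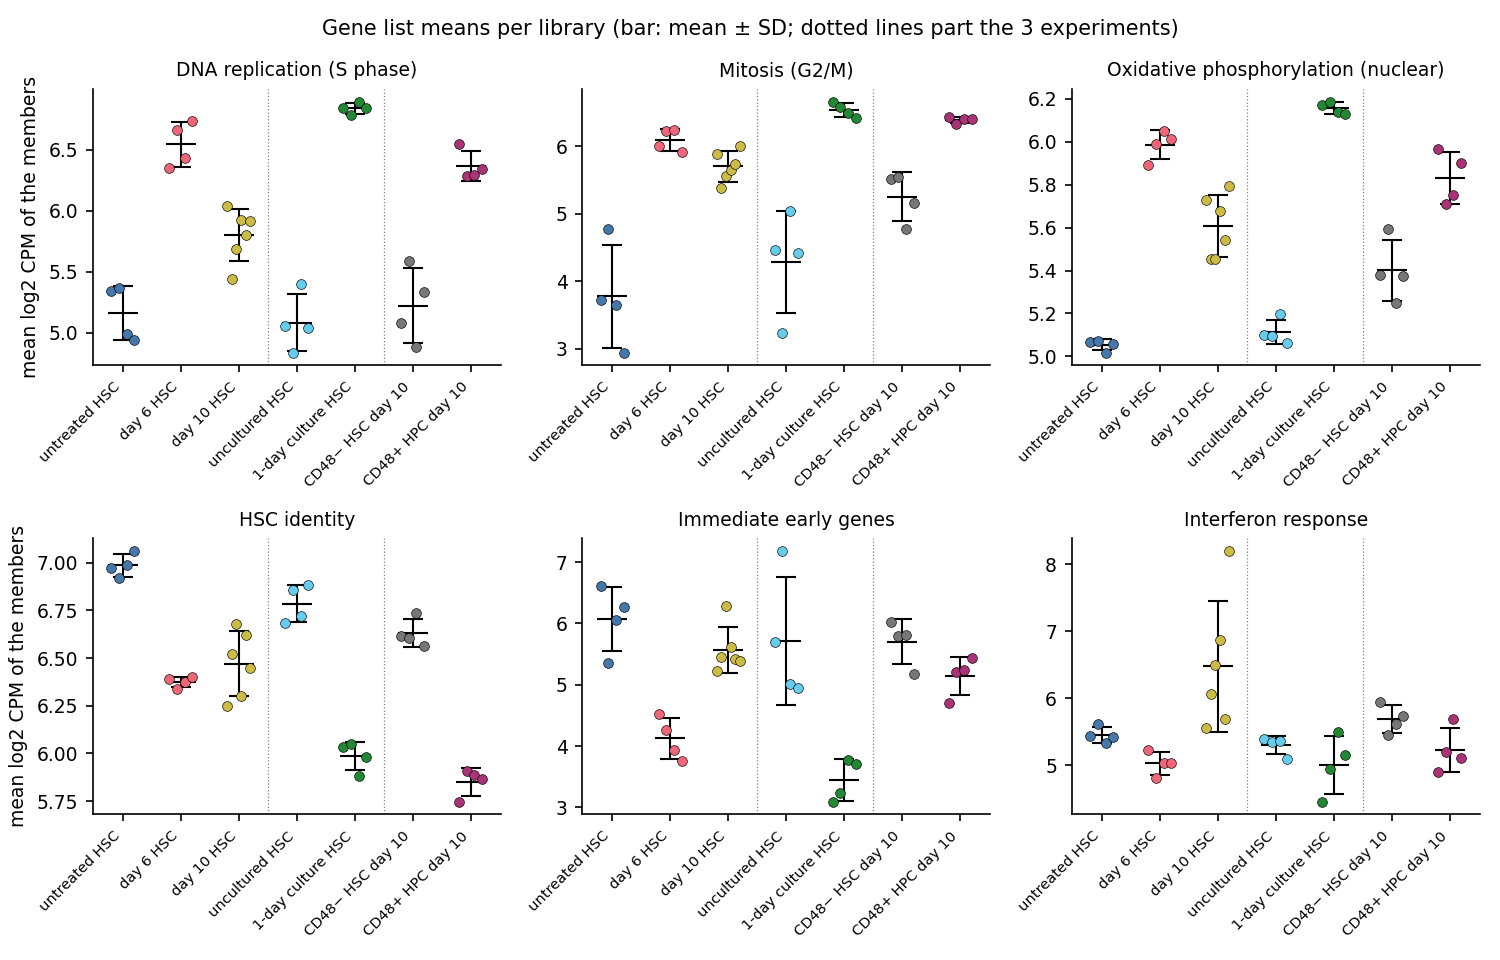
Mean log2 CPM of the measured members of 6 gene lists on the y axis, one point per library, with the mean and SD of each group on the x axis and dotted lines between the 3 experiments. The interferon list averages 6.48 ± 0.976 at day 10, with 1 library at 8.20, and 5.45 ± 0.122 in untreated HSCs.

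Day 10 was then compared with day 6, which asks what changed between these times. DNA replication, ribosome biogenesis and oxidative phosphorylation genes were lower at day 10 than at day 6, and interferon, inflammatory and immediate early genes were higher. The calls of these lists did not hold with an estimated correlation (adjusted p = 0.255 to 0.383). Socs3, a feedback inhibitor of cytokine signalling (gene 12702, chromosome 11, 117966079 to 117970342), rose from 6.09 ± 1.55 (SD, n = 4) to 70.2 ± 33.4 CPM (n = 6). Clca3a1 (gene 12722, chromosome 3, 144729677 to 144760977) rose from 4.98 ± 1.15 to 116 ± 60.2 CPM and Plac8 from 18.4 ± 6.84 to 221 ± 152. Enah, an actin regulator (gene 13800, chromosome 1, 181896384 to 182019980), fell from 41.0 ± 10.3 to 7.0 ± 2.29 CPM, and Cish, a cytokine-induced inhibitor, from 185 ± 45.9 to 57.9 ± 11.2.

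Of 56 DNA replication genes 52 fell, or 56 adjusted over the list alone, and of 65 mitosis genes 12 fell and 1 rose, or 10 and 0 (adjusted p = 2.03e-20 and 0.000483; adjusted p = 0.255 and 0.696 with an estimated correlation). The mitosis call was also lost with fry (adjusted p = 0.215). Pole fell from 317 ± 30.8 to 178 ± 20.7 CPM, Mcm3 from 507 ± 47.1 to 298 ± 40.4 and Mybl2 from 127 ± 12.8 to 59.5 ± 15.0. Mki67 was at 442 ± 47.6 against 612 ± 27.3 CPM (adjusted p = 0.0764), and Tyms fell from 118 ± 21.6 to 66.9 ± 10.7. Pyrimidine metabolism genes fell in 23 of 34 cases, oxidative phosphorylation genes in 52 of 77, TCA cycle genes in 17 of 28 and glycolysis genes in 12 of 23, with 2, 1, 0 and 4 that rose (adjusted p = 1.31e-06, 1.69e-14, 2.75e-08 and 0.00175). The lists had adjusted p = 0.255 to 0.262 with an estimated correlation, and adjusted over the list alone 23, 57, 20 and 14 fell and 4, 1, 1 and 4 rose. Cad fell from 704 ± 55.2 to 383 ± 55.6 CPM, Ndufa4 from 232 ± 9.93 to 146 ± 13.3 and Tpi1 from 265 ± 18.2 to 163 ± 12.1. Mitochondrial mRNA took 0.253 ± 0.0141% of reads at day 10, below all day-6 libraries (two-sided exact permutation p = 0.00476, the smallest possible, adjusted p = 0.0595). The intron share was 60.14% against 57.49% (two-sided exact permutation p = 0.0429, smallest possible 0.00476, adjusted p = 0.0975), with 5 of 6 day-10 libraries above all day-6 libraries. The mitochondrial and intron shares are of the same reads, so they are not independent.

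Of 57 ribosome biogenesis genes 50 fell, or 51 adjusted over the list alone, while of 79 cytosolic ribosomal protein genes 19 rose and 0 fell, also adjusted over the list alone (adjusted p = 2.79e-17 and 0.000338; adjusted p = 0.262 and 0.618 with an estimated correlation). Srm, spermidine synthase, fell from 305 ± 44.1 to 139 ± 23.5 CPM, and Rps27 rose from 436 ± 18.2 to 573 ± 16.9. Of 31 NRF2 target genes 14 fell, or 17 adjusted over the list alone (adjusted p = 0.00123; adjusted p = 0.255 with an estimated correlation), and Prdx1 fell from 508 ± 62.0 to 299 ± 37.7 CPM.

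Of 50 interferon genes 42 rose, or 45 adjusted over the list alone, and of 31 inflammatory and NF-kB genes 23 rose and 1 fell, or 24 and 2 (adjusted p = 1.11e-13 and 1.19e-09; adjusted p = 0.383 and 0.255 with an estimated correlation). Ifi27 rose from 28.8 ± 3.99 to 104 ± 32.6 CPM and Nfkbie from 13.3 ± 1.89 to 37.0 ± 10.2. Of 30 immediate early genes 25 rose and 1 fell, or 28 and 1 adjusted over the list alone (adjusted p = 2.41e-11; adjusted p = 0.255 with an estimated correlation), and Junb rose from 16.4 ± 6.26 to 89.0 ± 18.5 CPM. HSC identity genes rose in 18 of 50 cases and fell in 8, quiescence genes rose in 13 of 30 and fell in 1, and autophagy genes rose in 9 of 36 and fell in 1 (adjusted p = 0.0265, 0.000801 and 0.00686). With an estimated correlation they had adjusted p = 0.325 to 0.557, and adjusted over the list alone 20, 14 and 9 rose and 9, 2 and 1 fell. Adgrg1 rose from 2094 ± 123 to 3140 ± 334 CPM, Btg1 from 64.0 ± 13.3 to 161 ± 17.0 and Ulk1, an autophagy kinase, from 134 ± 10.4 to 241 ± 43.8.

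The myeloid, lymphoid, MHC class II and megakaryocyte lists were called higher at day 10. The numbers of genes that rose were 4 of 16 for myeloid, 5 of 11 for lymphoid and 3 of 11 for MHC class II genes, none falling, the same as adjusted over the list alone, and 7 of 25 for megakaryocyte genes, with 2 that fell, or 9 and 2. Their adjusted p-values were 0.00555, 0.0174, 0.0104 and, just under the threshold, 0.05, and with an estimated correlation adjusted p = 0.299, 0.255, 0.496 and 0.528. Prtn3, a neutrophil protease (gene 19152, chromosome 10, 79879667 to 79883174), rose from 12.8 ± 0.839 to 50.3 ± 10.1 CPM, Csf3r from 116 ± 14.8 to 340 ± 68.1 and Flt3 from 3.94 ± 1.65 to 21.7 ± 9.79. In all, 3949 genes (30.6%) passed, 1894 higher and 2055 lower, of which 478 and 171 changed at least 2-fold, and 2900 (22.5%, against 0.95% by chance) did not overlap. Median, mean and test differed in sign for the endothelial and macrophage lists, neither of them called. With intron reads the calls for glycolysis, NRF2, MHC class II and megakaryocyte genes were lost (adjusted p = 0.0516 to 0.62). The HSC identity call was lost without day-10 replicate 3 (adjusted p = 0.0764) or 5 (0.0781) or with the replicate block (0.0808), the lymphoid call without day-6 replicate 3 (0.0849) and the megakaryocyte call without any of several libraries (up to 0.176, without day-10 replicate 3) or with RLE (0.0506), with ranges of 0.00868 to 0.557, 0.00184 to 0.255 and 0.0137 to 0.528 over their alternatives. The cytosolic ribosomal protein list, called higher with total exon reads, was not called with unique exon reads (adjusted p = 0.299) or fry (0.0645) and was called lower with intron reads, and its adjusted p ran from 1.45e-11 to 0.618 over its alternatives.

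The culture comparison asked what 1 day in culture changed in HSCs of untreated mice. Cultured HSCs had more mRNA of cholesterol and fatty acid synthesis genes and of the growth and division genes raised at day 6. They had less mRNA of immediate early, HSC identity and quiescence genes. None of these list calls held with an estimated correlation (adjusted p = 0.255 and 0.305 for cholesterol and fatty acid synthesis, 0.188 to 0.553 for the others). Scd1, stearoyl-CoA desaturase (gene 20249, chromosome 19, 44394450 to 44407709), rose from 6.69 ± 2.69 to 577 ± 25.6 CPM (SD, n = 4 and 4), a log2 change of 6.42 (adjusted p = 3.72e-10). Hmgcs1, HMG-CoA synthase (gene 208715, chromosome 13, 119690351 to 119708260), rose from 31.9 ± 7.97 to 681 ± 21.5 CPM. Txnip, an inhibitor of thioredoxin and glucose uptake (gene 56338, chromosome 3, 96557957 to 96561857), fell from 1334 ± 118 to 85.6 ± 5.25 CPM. Id1 rose from 1.20 ± 0.772 to 39.7 ± 6.93 CPM and S100a4 from 1.82 ± 0.461 to 89.3 ± 15.6.

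Of 25 cholesterol synthesis genes 24 rose and 1 fell, also adjusted over the list alone, with a median log2 change of 3.01 (adjusted p = 3.55e-11; adjusted p = 0.255 with an estimated correlation). Lss rose from 31.4 ± 5.05 to 480 ± 40.5 CPM and Fdps from 13.4 ± 3.94 to 389 ± 10.8. Of 26 fatty acid synthesis and acetyl-CoA supply genes 19 rose and 3 fell, or 20 and 3 adjusted over the list alone (adjusted p = 2.16e-05; adjusted p = 0.305 with an estimated correlation). Acly, ATP citrate lyase, which makes cytosolic acetyl-CoA (gene 104112, chromosome 11, 100476352 to 100528000), rose from 218 ± 21.01 to 911 ± 11.6 CPM, and Fads2 from 51.0 ± 4.46 to 324 ± 16.2. At day 6 Acly rose by 0.37 on the log2 scale (adjusted p = 0.00044), Scd1 fell by 2.47 (adjusted p = 0.00593) and Hmgcs1 changed by -0.05 (adjusted p = 0.897).

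All 56 DNA replication genes rose in culture, as did 64 of 65 mitosis genes, the same numbers as adjusted over the list alone (adjusted p = 2.68e-18 and 1.68e-12; adjusted p = 0.255 and 0.499 with an estimated correlation). Pole rose from 90.5 ± 7.42 to 409 ± 3.59 CPM, Tyms from 31.9 ± 1.79 to 175 ± 12.6, Mki67 from 183 ± 78.5 to 625 ± 44.8 and Mybl2 from 21.95 ± 9.39 to 226 ± 16.0. Oxidative phosphorylation genes rose in 73 of 77 cases, TCA cycle genes in 26 of 28, glycolysis genes in 16 of 23 and pyrimidine metabolism genes in 23 of 34, with 1, 0, 5 and 6 that fell (adjusted p = 5.33e-17, 2.25e-07, 0.0056 and 0.00077). The lists had adjusted p = 0.188 to 0.255 with an estimated correlation, and adjusted over the list alone 73, 26, 16 and 24 rose and 1, 0, 5 and 6 fell. Cox5a rose from 34.3 ± 3.13 to 132 ± 9.27 CPM, Cs, citrate synthase, from 170 ± 9.65 to 415 ± 18.4 and Pkm from 600 ± 36.4 to 1833 ± 92.6. Ribosome biogenesis genes rose in 51 of 57 cases, ATF4 response genes in 29 of 40 and NRF2 target genes in 24 of 31, with 0, 5 and 3 that fell (adjusted p = 1.84e-14, 1.09e-05 and 1.05e-05). With an estimated correlation they had adjusted p = 0.188, 0.255 and 0.188, and adjusted over the list alone 52, 29 and 24 rose and 0, 6 and 3 fell. Mthfd2 rose from 3.66 ± 1.19 to 67.5 ± 10.8 CPM, Psat1 from 57.9 ± 7.61 to 275 ± 4.04 and Nqo1, an NRF2 target, from 14.8 ± 4.59 to 187 ± 17.2. Cdkn1a rose from 6.33 ± 3.99 to 28.2 ± 2.92 CPM. The intron share was 56.3 ± 0.16% against 66.4 ± 0.94% and the mitochondrial mRNA share 0.358 ± 0.0131% against 0.230 ± 0.0331% (both two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0794). Here too the shares are of the same reads, so they are not independent.

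HSC identity genes fell in 38 of 49 cases, quiescence genes in 19 of 28, immediate early genes in 24 of 28 and inflammatory genes in 17 of 29, with 5, 3, 1 and 4 that rose, all as adjusted over the list alone (adjusted p = 4.83e-07, 0.00107, 0.000212 and 0.0042). The lists had adjusted p = 0.255 to 0.553 with an estimated correlation. Sult1a1 fell from 186 ± 37.0 to 18.1 ± 1.31 CPM, Mllt3 from 320 ± 30.1 to 116 ± 6.73, Foxo3 from 606 ± 63.4 to 257 ± 19.7 and Traf1 from 42.5 ± 4.11 to 7.56 ± 2.06. The immediate early gene Fos fell from 742 ± 713 to 1.25 ± 1.32 CPM, a log2 change of -9.31 that was -8.425 without uncultured replicate 2 and -10.27 without cultured replicate 3. Procr fell from 57.7 ± 9.34 to 18.7 ± 1.65 CPM, Slamf1 from 24.3 ± 1.65 to 13.1 ± 2.30, and Cd48 was at 1.56 ± 0.696 against 2.497 ± 1.05 (adjusted p = 0.21).

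Several cell type lists fell in culture, namely lymphoid (7 of 9 fell, 1 rose), megakaryocyte (12 of 23 fell, 2 rose), endothelial (6 of 15 fell, 1 rose), macrophage (8 of 12 fell, 1 rose) and MHC class II genes (5 of 10 fell). Adjusted over the list alone 7, 12, 6, 8 and 4 fell and 1, 2, 0, 1 and 0 rose. Cultured libraries also had fewer genes detected (14500 against 14750 on average) and a lower share of unique reads (81.33% against 82.64%), below all uncultured libraries in all 4 (both two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0794). The adjusted p-values of the lists were 0.0263, 0.0406, 0.0486, 0.00478 and 0.0386, and with an estimated correlation adjusted p = 0.255, 0.631, 0.255, 0.255 and 0.521. Satb1 fell from 48.1 ± 4.01 to 4.92 ± 0.976 CPM and Tek from 53.7 ± 3.54 to 28.2 ± 1.17. Apoe, which macrophages also express, fell from 163 ± 11.3 to 20.8 ± 2.20 CPM, and Vcam1 was at 0 in all 4 cultured libraries against 9.64 ± 4.00, at least 22.9-fold lower. Of 15 erythroid genes 9 fell and 1 rose with no call for the list (adjusted p = 0.0815), and Hba-a2 was at 0 in the cultured libraries and at 406, 2.52, 651 and 4.77 CPM in uncultured replicates 1 to 4.

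In culture 8369 of 12386 genes (67.6%) passed, 4187 higher and 4182 lower, of which 1483 and 1893 changed at least 2-fold, and 7688 (62.1%, against 2.86% by chance) did not overlap. Median, mean and test differed in sign for the p53 list (13 rose and 15 fell of 39) and the cytosolic ribosomal protein list (19 and 21 of 79), neither of them called. With intron reads the calls for glycolysis, MHC class II, megakaryocyte, endothelial and macrophage genes were lost (adjusted p = 0.0633 to 0.31). Leaving out 1 library ended the megakaryocyte call (adjusted p = 0.138 without uncultured replicate 2, and 0.0751 with unique exon reads), the endothelial call (0.0743, 0.0517 and 0.0604 without uncultured replicates 2, 3 and 4, and 0.0682, 0.0505 and 0.0721 with the replicate block, RLE and no filter) and the MHC class II call (0.0617, 0.0799 and 0.0565 without uncultured replicate 4 and cultured replicates 1 and 2), with ranges of 0.00324 to 0.631, 6.23e-05 to 0.255 and 0.00206 to 0.521 over their alternatives.

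**Figure D4:**
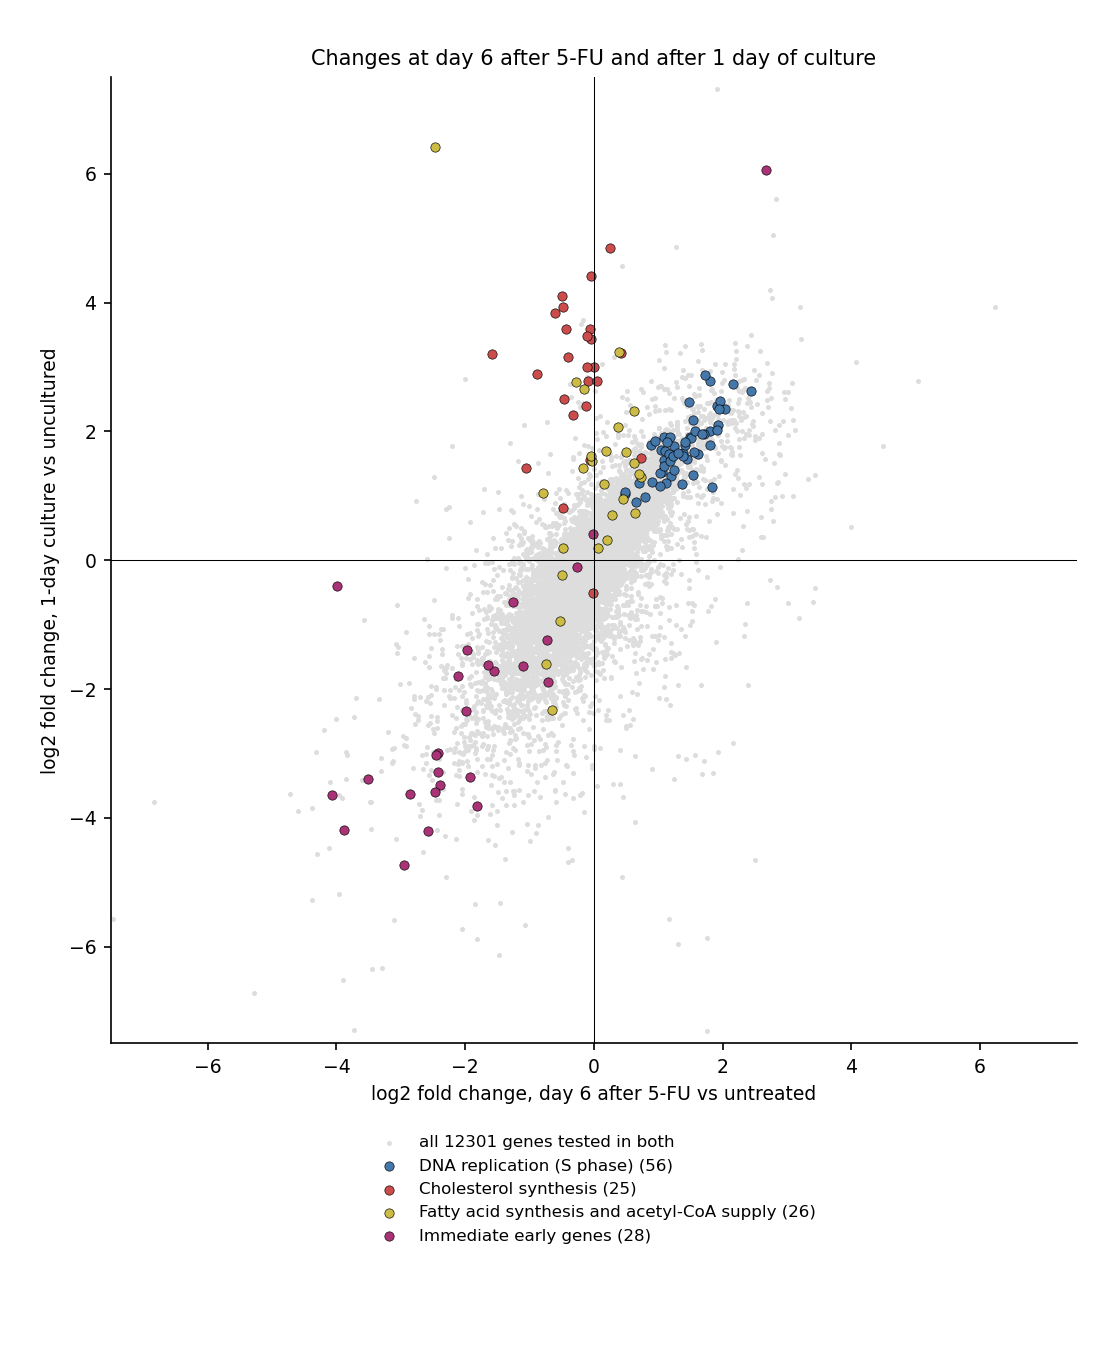
Log2 fold change of 12301 genes at day 6 after 5-FU on the x axis and after 1 day of culture on the y axis, one point per gene, with 4 gene lists in colour (7 genes lie outside the axes). DNA replication genes lie at the upper right and immediate early genes mostly at the lower left, while cholesterol synthesis genes have a median of 3.01 in culture and -0.11 at day 6.

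The last of the 5 comparisons asked how CD48+ HPCs differed from CD48− HSCs 10 days after 5-FU. CD48+ HPCs had more mRNA of cell division, respiration and myeloid genes, and less of HSC identity and interferon response genes. For these lists too the calls were lost with an estimated correlation (adjusted p = 0.188 to 0.528). The interferon call was also lost with fry (adjusted p = 0.0562, range 4.34e-10 to 0.528 over its alternatives), and the list's mean differed by -0.46 on the log2 scale (two-sided exact permutation p = 0.0857, smallest possible 0.0286). Cd48 itself (gene 12506, chromosome 1, 171681420 to 171705257) was at 51.3 ± 4.66 CPM (SD, n = 4) against 3.05 ± 1.79 (n = 4), a log2 change of 4.10 (adjusted p = 2.34e-05). Vwf, von Willebrand factor (gene 22371, chromosome 6, 125552935 to 125686679), fell from 859 ± 157 to 141 ± 19.9 CPM, and Neo1, a netrin receptor (gene 18007, chromosome 9, 58874679 to 59037162), from 161 ± 39.3 to 14.9 ± 3.36. Tespa1 (gene 67596, chromosome 10, 130322826 to 130363469) rose from 3.43 ± 0.9497 to 52.4 ± 6.43 CPM and Cd244 from 6.23 ± 2.76 to 50.2 ± 13.3.

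Of 56 DNA replication genes 55 rose and of 65 mitosis genes 64 rose, or 56 and 64 adjusted over the list alone (adjusted p = 4.48e-26 and 4.66e-27; adjusted p = 0.255 and 0.262 with an estimated correlation). Mcm10 rose from 27.1 ± 6.32 to 92.1 ± 9.71 CPM, Nusap1 from 21.5 ± 3.96 to 52.4 ± 3.49, Mki67 from 343 ± 78.8 to 684 ± 22.1 and Tyms from 40.2 ± 6.996 to 94.2 ± 5.94. Pyrimidine metabolism genes rose in 20 of 34 cases, oxidative phosphorylation genes in 45 of 77, TCA cycle genes in 13 of 28 and ribosome biogenesis genes in 39 of 57, with 4, 0, 0 and 0 that fell (adjusted p = 7.8e-05, 2.52e-13, 1.26e-05 and 1.11e-13). With an estimated correlation they had adjusted p = 0.28 to 0.383, and adjusted over the list alone 22, 56, 19 and 47 rose and 6, 1, 0 and 0 fell. Rrm2 rose from 89.9 ± 24.1 to 255 ± 6.63 CPM, Cox5a from 42.0 ± 3.85 to 72.6 ± 7.59 and Myc from 93.3 ± 19.2 to 232 ± 42.5. Of 38 ATF4 response genes 19 rose and 3 fell, or 21 and 4 adjusted over the list alone (adjusted p = 0.00119; adjusted p = 0.307 with an estimated correlation), and Psat1 rose from 77.9 ± 11.6 to 147 ± 24.1 CPM. The cytosolic ribosomal protein list was called higher (adjusted p = 0.0414; adjusted p = 0.835 with an estimated correlation), although 2 of 79 genes rose, 0 adjusted over the list alone, and its median log2 change was 0.08. The intron share was 59.7 ± 1.63% in HPCs against 63.6 ± 2.34% (two-sided exact permutation p = 0.0571, smallest possible 0.0286, adjusted p = 0.11).

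Of 49 HSC identity genes 33 fell and 0 rose, or 41 and 0 adjusted over the list alone, and of 29 quiescence genes 11 fell, or 13 (adjusted p = 1.04e-16 and 8.17e-05; adjusted p = 0.188 and 0.325 with an estimated correlation). Ctnnal1 fell from 63.5 ± 3.00 to 21.2 ± 1.74 CPM, Fgd5 from 333 ± 25.7 to 126 ± 13.0 and Prdm16 from 161 ± 17.9 to 75.4 ± 4.77. Of 48 interferon genes 22 fell and 1 rose, or 26 and 2 adjusted over the list alone, and of 29 immediate early genes 15 fell and 1 rose, or 19 and 1 (adjusted p = 1.09e-05 and 0.000104; adjusted p = 0.528 and 0.496 with an estimated correlation). The guanylate-binding protein genes Gbp2 and Gbp7 and the immediate early gene Klf6 had log2 changes of -0.93, -0.70 and -0.87. Slamf1 fell from 54.7 ± 9.33 to 29.1 ± 1.94 CPM and Procr from 85.5 ± 16.7 to 45.7 ± 5.56, within the gate that keeps CD150+ and EPCR+ cells.

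Of 19 myeloid and neutrophil progenitor genes 12 rose and 1 fell, or 14 and 1 adjusted over the list alone, and of 12 lymphoid genes 3 rose, or 5 with 1 falling (adjusted p = 5.8e-06 and 0.0223; adjusted p = 0.255 and 0.325 with an estimated correlation). Nkg7 rose from 20.4 ± 3.47 to 122 ± 8.88 CPM and Cebpa, a myeloid transcription factor, from 2.49 ± 0.5997 to 17.5 ± 4.38. Mpo, myeloperoxidase, was at 163 ± 133 against 0.333 ± 0.163 CPM, with 333, 18.2, 113 and 189 in replicates 1 to 4, and its log2 change of 8.94 was 8.32 without CD48+ replicate 1. Of 16 endothelial genes 7 fell and 1 rose, or 7 and 2 adjusted over the list alone (adjusted p = 0.0106; adjusted p = 0.255 with an estimated correlation). Tie1 fell from 510 ± 25.5 to 255 ± 17.7 CPM and Sox18 from 19.97 ± 4.62 to 6.45 ± 1.22. Of 19 macrophage genes 10 rose and 0 fell, or 15 and 0 adjusted over the list alone (adjusted p = 0.000132; adjusted p = 0.528 with an estimated correlation). Csf1r was at 53.7, 49.0, 166 and 18.9 CPM in CD48+ replicates 1 to 4 and at 10.0, 9.87, 34.8 and 4.99 in CD48− replicates 1 to 4.

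In CD48+ HPCs 3373 of 12719 genes (26.5%) passed, 1781 higher and 1592 lower, of which 429 and 458 changed at least 2-fold, and 3458 (27.2%, against 2.86% by chance) did not overlap. Median, mean and test differed in sign for the fatty acid oxidation, megakaryocyte and erythroid lists, none of them called. The count of genes was 2139 without CD48+ replicate 1. With intron reads the calls for oxidative phosphorylation, the TCA cycle, ATF4, myeloid, lymphoid and endothelial genes were lost (adjusted p = 0.0617 to 0.43). The ribosomal protein call was lost with unique exon reads (adjusted p = 0.12), with fry (0.523) and without any 1 of CD48− replicates 3 and 4 and CD48+ replicates 1, 2 and 4 (adjusted p = 0.108, 0.721, 0.0539, 0.153 and 0.138, range 6.33e-05 to 0.835 over its alternatives).

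**Figure D5:**
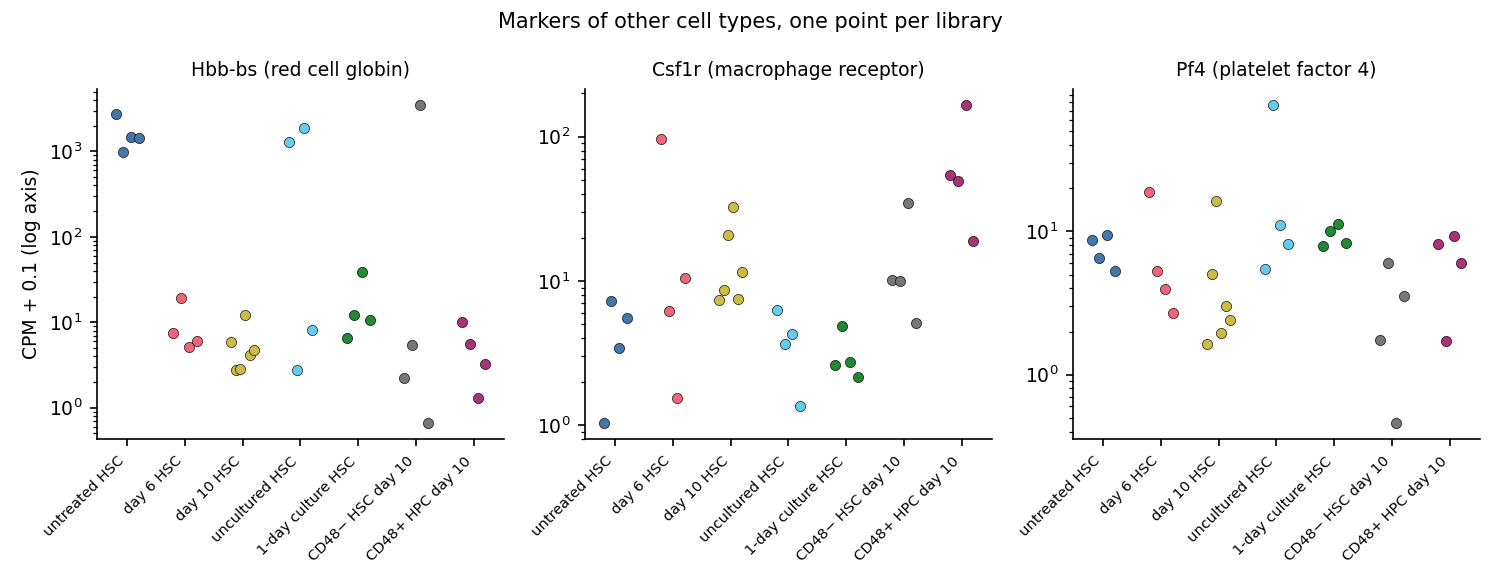
CPM plus 0.1 on a log y axis of Hbb-bs, Csf1r and Pf4, transcripts typical of red cells, macrophages and platelets, one point per library and one column per group on the x axis. Hbb-bs is between 998 and 2719 CPM in untreated HSCs, near 1306 and 1867 in 2 uncultured libraries and at 3509 in 1 CD48− library.

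Changes were then compared between contrasts. Of 12886 genes, 3793 passed at both day 6 and day 10, of which 3740 moved in the same direction (1984 up, 1756 down) and 53 in opposite directions, where independent calls would give 1257 in the same direction. The log2 changes correlated across genes (Pearson r = 0.722, Spearman rho = 0.741), where genes are not independent replicates. Both times were measured against the same untreated libraries, and 20 simulated data sets with no treatment effect gave a mean r of 0.551. The covariance of the log2 changes, which unlike r keeps their size, was 0.496. It was 0.044 on average and at most 0.047 in the simulations, so shared controls alone gave little of it. The simulations had 0 shared genes, but data with no effect yield few calls, so that count says little. With 2 untreated libraries for each time, 1491 to 2041 genes passed in both and moved in the same direction over the 6 ways to divide them, where 462 to 667 were expected, and r was 0.597 to 0.658.

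Day 6 and culture, which have separate controls, shared 5468 of 12301 genes, 5320 in the same direction (2783 up, 2537 down) and 148 in opposite directions, where 2186 would be expected, with r = 0.738 and rho = 0.785 across genes. Day 10 and the CD48 comparison, of separate libraries, shared 1944 of 12529 genes, 1803 in the same direction (1048 up, 755 down) and 141 in opposite directions, where 636.9 would be expected, with r = 0.437 and rho = 0.498 across genes. Mki67 and Tyms rose in both contrasts of each of these pairs.

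Groups with matching labels were compared between experiments as a check. Untreated and uncultured HSCs differed in 193 of 12578 genes (113 higher in uncultured, 80 lower), with 2135 at an unadjusted p under 0.05. Day-10 HSCs of the 5-FU experiment and CD48− HSCs at day 10 differed in 461 of 12688 genes (183 higher in the CD48 experiment, 278 lower), with 3263 at an unadjusted p under 0.05. Rpl29, a ribosomal protein gene, and Sod1, superoxide dismutase, both chosen after their values were seen, were higher by 0.98 and 0.66 on the log2 scale in uncultured HSCs and by 0.80 and 0.72 in the CD48 experiment. The first count was 121, 76, 65 and 42 without untreated replicates 1 to 4 and 111, 117, 31 and 44 without uncultured replicates 1 to 4. The second was 80, 906, 25, 53 and 178 without day-10 replicates 1, 2, 4, 5 and 6 and 8, 755 and 10 without CD48− replicates 1, 2 and 3.

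The p-values measure the spread between libraries of 100 cells, which may be technical as well as biological, since the sources used here do not say whether replicates came from different mice. Of the 86 list calls, 0 held when the correlation between genes was estimated from the residuals in place of the preset value of 0.01, where 27 lists had an unadjusted p under 0.05 in camera. With that estimate, camera gave cholesterol synthesis an adjusted p of 0.255 in culture. It gave 0.00326 for the difference between the culture and day-6 effects, reported below, in a fit of all 30 libraries. How far the loss of calls comes from the number of libraries in a fit was not tested. A self-contained test (fry), which asks whether a list's genes move on balance one way, gave an adjusted p under 0.05 for 15, 12, 15, 20 and 12 of the called lists in the 5 comparisons. The 12 calls lost with fry (adjusted p = 0.0529 to 0.523) were those for macrophage genes at day 6, for ribosome biogenesis, interferon and macrophage genes at day 10, and for HSC identity, mitosis, ribosomal protein and megakaryocyte genes between day 10 and day 6. In the CD48 comparison they were those for ribosomal protein, interferon (0.0562), immediate early and macrophage genes. Its mixed version asks whether genes change in either direction, and neither version compares a list with other genes.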

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

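The tests of the 3 patterns weighed below and the comparison of effects between experiments were chosen only after the results were seen, while the splits of the libraries within comparisons were planned.

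In single libraries, 10 of 112 group and measure combinations had a highest or lowest library far from the others, where chance gives about 1 in 20. The myeloid list averaged 4.253 log2 CPM in untreated replicate 3 against 2.374 to 2.527 in the others. The endothelial list averaged 3.112 in untreated replicate 2 against 3.516 to 3.543. In day-6 replicate 3 the intron share was 56.2% against 57.87 to 58.01% and the mitochondrial mRNA share 0.362% against 0.316 to 0.322%. In day-10 replicate 3 the immediate early list averaged 6.277 against 5.232 to 5.618 and the stromal list 4.56 against 1.507 to 2.253. The erythroid list averaged 3.9 in day-10 replicate 4 against 1.694 to 1.93, and 5.423 in CD48− replicate 3 against 1.664 to 1.784. The megakaryocyte list averaged 6.326 in uncultured replicate 2 against 4.649 to 4.779. The ribosomal protein list averaged 8.699 in cultured replicate 2 against 8.688 to 8.689.

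Effects at day 6 and day 10, both against untreated HSCs, differed by the camera test of day 10 against day 6 for 4 lists whose medians had opposite signs. The median log2 change of the interferon list was -0.54 at day 6 and 1.35 at day 10, with a median gene difference of 1.676 (adjusted p = 1.11e-13). That of the inflammatory list went from -0.74 to 0.31, with a difference of 0.805 (adjusted p = 1.19e-09). The NRF2 list had 0.26 and -0.04, with a difference of -0.285 (adjusted p = 0.00123), and the autophagy list -0.09 and 0.12, with a difference of 0.172 (adjusted p = 0.00686). With an estimated correlation the adjusted p was 0.383, 0.255, 0.255 and 0.383.

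Intron reads, which the comparisons above do not use, also gave calls in edgeR. They were 3598 genes at day 6 (1815 higher, 1783 lower), 2446 at day 10 (1244 and 1202) and 2315 between day 10 and day 6 (1206 and 1109). They were 6013 in culture (2972 and 3041) and 1595 between CD48+ HPCs and CD48− HSCs (876 and 719). The mitochondrial mRNA share was 0.3292% at day 6 against 0.2498%, and 0.3578% in culture against 0.2302% (two-sided exact permutation p = 0.0286 each, the smallest possible). It is a share of reads that include intron reads, and the intron share was lower in the same libraries. A lower intron share can by itself raise the mitochondrial share, and a difference beyond that was not tested.

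Erythroid genes were lower at day 6. Of the 19 members that fell, 11 were at or below the highest day-6 library in at least 1 of the 8 libraries of untreated mice, and 42.1% were above it in all 8, where 100 random sets of genes that fell, matched in change and level, gave 47.4 to 94.7%. The share was below that of every random set. It was close to the lowest, and the random genes were not matched in how they vary together. The mean of the whole list was at least 1.954 log2 CPM in the 8 libraries of untreated mice and at most 1.649 at day 6. Such a spread between libraries would also come from HSCs that express these genes in varying numbers. The test therefore cannot argue against lower expression in the HSCs themselves. Erythroid cells or their RNA in some libraries of untreated mice would give this spread, and Hbb-bs reached 2719 CPM and Hba-a2 700 CPM there. For the 8 members above day 6 in all 8 libraries, among them Hba-a2, Slc4a1 and Ermap, lower expression in the HSCs themselves cannot be told apart from such RNA, since each library pools 100 cells. The Lineage− gate is meant to remove mature cells, but how many erythroid cells it left was not tested.

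Macrophage genes were higher in CD48+ HPCs. Members moved together between libraries of a group, with a mean correlation of 0.733 where 200 random lists reached at most 0.196. Macrophages or their RNA in some libraries would give this. So would HPCs that express these genes in varying numbers, so the correlation cannot tell the 2 apart. Csf1r and C1qb were at 166 and 141 CPM in CD48+ replicate 3. Expression by the HPCs themselves stays open, since the groups' means differed by 1.65 on the log2 scale with a two-sided exact permutation p of 0.0857 (smallest possible 0.0286) and 1 of 10 risen members did not overlap. The Lineage− gate is meant to remove mature cells, but how many macrophages it left was not tested.

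Interferon genes were higher at day 10. Of the 32 that rose, 26 still passed without day-10 replicate 6, which argues against a single library as the whole source, and 26 without replicate 4. Without replicate 6 the median log2 change of the list went from 1.354 to 0.667. A state of day-10 HSCs may be involved, but CD48− HSCs of the other experiment differed from untreated HSCs by 0.236 in the list's mean with a two-sided exact permutation p of 0.0857 (smallest possible 0.0286), so this stays open. The day-10 libraries differed from untreated by 1.027 (two-sided exact permutation p = 0.0524, smallest possible 0.00476). The day-6 libraries differed from untreated by -0.424 (two-sided exact permutation p = 0.0286, the smallest possible).

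By a rule of under 0.05 of the splits, chance was excluded for the number of genes in the 5 comparisons, where 1 split of those tried, the real one, gave as many. For day 6, culture and CD48 there were 35 splits, so 1 of 35 was the smallest share possible. The splits do not test a difference in sorting or preparation that follows the groups. The real counts and the highest other split were 6622 and 0 at day 6, 4893 and 1869 at day 10, 3949 and 1972 for day 10 against day 6, 8369 and 0 in culture and 3373 and 1 for CD48. In the checks between experiments the real split also gave the most genes, for untreated against uncultured HSCs (193 and 70) and for the day-10 HSCs of both experiments (461 and 447). These 2 counts fell to 3 and 9 with the replicate block and to 2 and 4 with the doubted libraries left out. Given these falls, the rank of the real split alone does not exclude chance for the 2 counts. More fitted terms or fewer libraries also lower such counts, so the falls do not show that the experiments are alike. Over all splits, chance was not excluded for the number of lists, where 7 of 35 splits gave at least 16 lists at day 6 (highest other 19) and 12 of 100 at least 15 at day 10 (17). The numbers were 6 of 100 with at least 19 for day 10 against day 6 (21), 5 of 35 with at least 20 in culture (23) and 7 of 35 with at least 16 for CD48 (17). At day 6 and in culture all other splits with as many lists exchanged 1 library and so kept part of the real difference, and those that exchanged 2 gave 2 to 8 and 3 to 9 lists. These counts therefore do not show that chance gives 16 or 20 lists. Splits that exchanged 2 libraries gave up to 17 lists at day 10 and for CD48, and those that exchanged 3 gave up to 21 for day 10 against day 6.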

How the results depend on the processing

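The alternatives with unique exon reads, intron reads, entries as deposited, fry and 8 libraries left out together, and all alternatives of the checks between experiments, were chosen only after seeing the data. Counts of genes in the 5 comparisons stayed within 1.5 times under RLE size factors, no filter, DESeq2, the replicate block, 1 fit of all libraries, the 2 groups alone (for the 3 comparisons of the 5-FU experiment, as the others hold 2 groups), the controls of the other experiment, unique exon reads and entries as deposited. They were 6397, 3639, 3271, 8141 and 2657 with the replicate block, although replicates of the same number were no more alike than others, and 6882, 4780, 8650 and 2507 with the controls of the other experiment (not applicable to day 10 against day 6), of which 5277, 3299, 7341 and 1515 were among the calls above. With the 8 doubted libraries left out they were 6064, 3627, 3335, 7978 and 2266. Intron reads gave 3598 genes at day 6, 2446 at day 10, 2315 for day 10 against day 6 and 1595 for CD48, and the cause was not tested. Leaving out 1 library gave 5945 to 6321, 3997 to 5049, 2838 to 4198, 7942 to 8292 and 2139 (without CD48+ replicate 1) to 3496 genes. In simulated data 1.5-fold changes were recovered in 35.8 to 59.7% of cases. Far fewer genes were changed there than passed in the data, so this does not measure the share missed here.

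Untreated against uncultured HSCs gave 651 genes with DESeq2, 3 with the replicate block, 122 with unique exon reads, 1 with intron reads, 2 with the doubted libraries left out and 31 (without uncultured replicate 3) to 121 (without untreated replicate 1) with 1 library left out. The day-10 HSCs of both experiments gave 1456 with DESeq2, 9 with the replicate block, 1 with intron reads, 4 with the doubted libraries left out and 8 (without CD48− replicate 1) to 906 (without day-10 replicate 2). Genes that passed in both and moved in the same direction were 1504, 2611 and 620 with intron reads for day 6 and day 10, day 6 and culture, and day 10 and CD48, against 3740, 5320 and 1803, and 1047 for the last with the doubted libraries left out. The cause was not tested.

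List calls numbered 86, and 0 with camera at an estimated correlation (27 at an unadjusted p under 0.05), against 86 with fry, which lost 12 and gained 12. They were 84 with RLE (2 lost), 82 with unique reads (5 lost, 3 gained, 2 not tested), 90 with the replicate block (3 lost, 7 gained), 92 with the doubted libraries left out, 70 with intron reads (30 lost, 13 gained, 1 called on a list tested with intron reads alone, 1 reversed, that of ribosomal proteins for day 10 against day 6) and 84 to 88 with 1 library left out. No filter lost 1 call and gained 16. Calls lost with the doubted libraries left out were those for macrophage genes at day 6, ATF4 at day 10, HSC identity and megakaryocyte genes for day 10 against day 6 and MHC class II in culture. Uncultured replicates 2 and 3 and day-10 replicate 4, with high megakaryocyte or erythroid list means, stayed in.

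Of the values of named genes reported, 272 had the same call with intron reads, 90 lost the call, 2 gained it and 22, of 18 genes, reversed, of which 1 passed. The cause was not tested. The log2 changes at day 6 were -0.29 for Eif5a and -0.18 for Cdkn1a. At day 10 they were -0.042 for Ndufa4, -0.039 for Atp5b, -0.007 for Uqcrc1, -0.045 for Mdh2, -0.11 for Sdhd, -0.076 for Rpl41, -0.20 for Rpl7a, -0.28 for Eif5a, -0.18 for Hspe1 and -0.024 for Spi1. For day 10 against day 6 they were -0.20 for Rps9, 0.48 for Prdx6, -0.022 for H2-DMa, 0.17 for Ebp, -0.54 for Apoe and 1.48 for Cdkn1a, which passed (adjusted p = 0.0392). In culture they were -0.20 for Pcna, -0.49 for Eif5a and 0.21 for H2-DMa, and for CD48 -0.075 for Idh2.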

Other observations

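The comparison of effects between experiments, its splits and its fits with 1 library left out were chosen only after the results were seen. Culture and day 6 were set side by side in 1 edgeR fit of all 30 libraries, which tests for each gene whether the culture effect and the day-6 effect differ. The mRNA of lipid synthesis genes separated them. Of 25 cholesterol synthesis genes 24 had a higher effect in culture than at day 6 and 1 a lower one, with a median difference of 3.08 on the log2 scale (camera adjusted p = 1.42e-42; adjusted p = 0.00326 with an estimated correlation). Of 26 fatty acid synthesis genes 18 were higher and 3 lower (median 0.93, adjusted p = 6.21e-16; 0.00326 with an estimated correlation), and of 31 NRF2 targets 13 were higher (median 0.42, adjusted p = 9.67e-09; 0.00843 with an estimated correlation). The difference was 8.87 for Scd1 (adjusted p = 6.08e-10), 4.44 for Hmgcs1 (adjusted p = 7.01e-11) and 1.67 for Acly (adjusted p = 4.37e-11). The effect on fatty acid oxidation genes was lower in culture in 10 of 29 cases and higher in 2 (adjusted p = 0.000259; adjusted p = 0.0515 with an estimated correlation). That on macrophage genes was lower in 13 of 19 cases (adjusted p = 1.77e-09; adjusted p = 0.314 with an estimated correlation), with a median of -4.106 that was -3.423 without day-6 replicate 1, whose list mean of 5.461 log2 CPM was the highest of the day-6 libraries (2.593 to 4.055 in the others). Of the other lists called (adjusted p = 2.38e-05 to 0.0462; adjusted p = 0.171 to 0.693 with an estimated correlation), few members passed: 9 of DNA replication, 5 of ribosome biogenesis, 7 of ATF4 and 6 of hypoxia genes were higher, with 0, 0, 1 and 1 lower. Lower were 7 quiescence, 7 myeloid and 6 endothelial genes, with 1, 2 and 0 higher. The myeloid list averaged 5.263 and 4.87 log2 CPM in uncultured replicates 1 and 4 and 2.52 in replicates 2 and 3, and its median difference of -1.999 was -1.485 and -1.714 without replicate 1 or 4 (adjusted p = 0.0232 and 0.0159). The quiescence call was lost without uncultured replicate 2 (adjusted p = 0.0724), and the hypoxia call without untreated replicate 4, day-6 replicate 3 or 4 or uncultured replicate 4 (adjusted p = 0.0595, 0.0518, 0.0597 and 0.0612).

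Of 13468 genes, the effects of culture and day 6 differed for 2037, 856 higher and 1181 lower in culture. Over all splits, chance was not excluded for this count, since 6 of 100 gave as many, with 3811 the highest other. The 5 others exchanged controls alone and kept the difference between cultured and day-6 libraries, so they do not show that chance gives 2037 genes. The 94 splits that exchanged treated libraries gave at most 229. The CD48 effect and the day-10 effect differed for 1453 genes, 621 higher and 832 lower. Of 100 splits 1, the real one, gave as many, and the highest other gave 169. All 99 others exchanged CD48+ HPC libraries with day-10 HSC libraries, and none exchanged controls alone. They test whether those cells differ, so they cannot exclude chance for the difference of effects. Interferon genes were lower in the CD48 effect in 30 of 50 cases (median difference -1.65, adjusted p = 1.13e-15; adjusted p = 0.45 with an estimated correlation), and the median was -1.006 without day-10 replicate 6 (adjusted p = 1.29e-16). DNA replication genes were higher in 12 of 56 cases (adjusted p = 1.57e-10; adjusted p = 0.488 with an estimated correlation) and ribosome biogenesis genes in 10 of 57 (adjusted p = 1.77e-09; adjusted p = 0.495 with an estimated correlation). Mitosis genes went the other way, with 6 of 65 lower and 1 higher (median -0.579, -1.08 without untreated replicate 2 and -0.374 without untreated replicate 4; adjusted p = 1.11e-06; adjusted p = 0.696 with an estimated correlation), and HSC identity genes were lower in 15 of 50 cases and higher in 2 (adjusted p = 0.000997; adjusted p = 0.488 with an estimated correlation). The other lists called (adjusted p = 0.000366 to 0.0462; adjusted p = 0.171 to 0.75 with an estimated correlation) had few members that passed. They were 7 inflammatory, 7 endothelial, 4 fatty acid oxidation and 1 of 77 oxidative phosphorylation genes, all lower, 2 of 28 erythroid genes, both higher, 8 lymphoid genes higher and 2 lower, and 2 myeloid genes higher and 2 lower. The oxidative phosphorylation call was lost without day-10 replicate 1 or 6, CD48− replicate 2 or CD48+ replicate 2 or 3 (adjusted p = 0.0625 to 0.263). The myeloid call was lost without untreated replicate 3, day-10 replicate 1, 2 or 5, CD48− replicate 2 or 4 or CD48+ replicate 1 (adjusted p = 0.0507 to 0.147).

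Of the myeloid genes of uncultured HSCs, Mpo was at 1676 and 1025 CPM in replicates 1 and 4 and at 2.07 and 0.450 in replicates 2 and 3. Oas2 was at 278, 111, 205 and 241 CPM in CD48− replicates 1 to 4, and at 61.3, 83.2, 40.5 and 32.0 in untreated replicates 1 to 4, both of different experiments, while the mean of the whole interferon list differed by 0.236 with 2 of 4 CD48− libraries above all untreated ones (two-sided exact permutation p = 0.0857, smallest possible 0.0286).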
